A study of Mus musculus with 30 samples.

How the data were processed

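RNA of brain, heart, kidney and vessel from mice given angiotensin II for 0, 1, 3 or 7 days was hybridized to Affymetrix whole-genome mouse arrays, 30 in all and in 15 groups. Groups, tissue, day and replicate number were taken from the sample labels. The deposited values are intensity values on a linear scale, with 1 value per probe set and array, made with Affymetrix Expression Console per the submitters' processing notes. The algorithm, version and settings of that step are not given in the sources used here. The values ranged from 3.18 to 22424 and the array medians from 35.2 to 37.8, so the arrays had been normalized to a common scale before deposit. No further normalization was applied.

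Of 45101 probe sets, 64 controls were left out, 34945 carried a single gene symbol, 932 several symbols and 9160 none. Only those with a single symbol were tested as genes; symbols were compared with the current annotation by Entrez identifier (34754 matched, 0 changed). Each of 18193 genes was represented by the probe set with the highest mean over all arrays (9010 genes had several). Values were analysed as log2(value + 16), which understates changes of weak signals. A gene was tested in a tissue when its value lay above the 40th percentile of the array on at least as many arrays as the smallest group holds, which left 14040 genes in heart, 14214 in kidney, 14109 in brain and 14295 in vessel.

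Heart (12 arrays), kidney (8) and brain (6) were each fitted by group means in limma 3.58.1 under R 4.3.3, with moderated tests of each contrast, Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05 on adjusted p. An F test over the 3 contrasts with day 0 asked for a change at any time in heart. Differences of response between tissues were contrasts of contrasts in a joint fit of 26 arrays and 11 groups. This fit gave all tissues a single estimate of spread per gene, and a gene was included when it passed the filter in either tissue compared. Vessel, with single arrays, was given as differences from the day 0 array without tests.

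In all, 37 gene lists with 868 members, 798 of them on the array, were fixed before the data were examined, as were the comparisons, tests, alternatives and the rule for named genes. They cover neutrophils, monocytes and macrophages, T and NK cells, B cells, MHC class II, chemokines and cytokines, extracellular matrix, cell cycle, interferon response, renin-angiotensin-aldosterone, glucocorticoid response, circadian clock, immediate early genes, heat shock, endothelium, red cells, smooth muscle, adipocytes, skeletal muscle, fatty acid oxidation, oxidative phosphorylation, and parts of heart, kidney and brain. Each list was tested with limma's camera at a preset correlation of 0.01 and at an estimated correlation, members were counted over all genes, and adjustment was repeated over the list alone. In vessel the list median was placed among 10000 random lists matched on expression, as a description that leaves out the correlation among genes of a list.

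The rule named, for each comparison with day 0, the 10 largest rises and 10 largest falls past the threshold whose treated arrays all lie on the same side of all day 0 arrays. It added up to 4 members of each list past the threshold by size, or up to 2 with the smallest p where none passed, and Agtr1a, Agtr1b, Agtr2, Ren1, Agt, Ace, Nppa and Nppb. For later times against earlier and for tissue differences it named the 5 largest rises and falls, or the 3 smallest p where none passed. For vessel it named the 10 highest and 10 lowest genes shared by the 3 treated arrays, with list members. The text names fewer where a ranking was long. Genes chosen after their values were seen are so described.

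Alternatives were no filter, quantile normalization again, the mean of all probe sets of a gene, trended and robust variances, a replicate block, added values of 1 and 64, the joint fit, only the groups compared, and each array left out in turn. Leaving out kidney arrays with adrenal markers, using the adipocyte median as a covariate and treating arrays of the same day and number as a correlated block were added after the data were seen. When an array was left out of a pair, the lone array was assumed to vary like the other groups. The code was tested on simulated data in which 200 genes were changed by 1.5, 2 or 4-fold. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, matplotlib 3.10.9 and the R package data.table, version 1.17.8.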

Results

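Gene expression was measured on 30 arrays of RNA from brain, heart, kidney and vessel of male C57BL/6 mice. The mice received angiotensin II, the peptide hormone that raises blood pressure through vasoconstriction and aldosterone release, from an implanted osmotic pump at 1500 ng per kg per minute. Organs were taken after 1, 3 or 7 days, and a day 0 group had no angiotensin II. Heart had 3 arrays at each of the 4 times, kidney 2 at each, brain 2 at days 0, 3 and 7, and vessel 1 at each time. The labels number the arrays as biological replicates, but they do not say which organs came from the same mouse or whether day 0 mice carried a pump. Each array held 45101 probe sets, with a median intensity between 35.2 and 37.8, and the small number of arrays limits the precision of every difference. Changes are differences of log2(intensity + 16), so those of weakly expressed genes are understated.

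The series title asks how expression in each tissue changes over 7 days of angiotensin II. In heart, 920 of 14040 genes differed from day 0 at any time by the limma F test, and 3482 had an unadjusted p under 0.05. Genes of cardiac muscle stress moved at every time and genes of inflammation and acute cell stress at day 1. Lists of extracellular matrix and cell division genes had their highest medians at day 3, but these differed between the day 3 replicates. No cell division gene of the list was called at day 3 over all genes, and no gene was called between day 3 and day 7. The count of 920 was 51 without day 1 replicate 1, 176 without day 1 replicate 2 and 2671 without day 1 replicate 3. It was 1399 without day 3 replicate 1, 407 without day 3 replicate 2, between 426 and 529 without each day 7 replicate, 257 without day 0 replicate 1, 249 without day 0 replicate 2, 455 with a replicate block and 1680 in a joint fit of 3 tissues.

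**Figure D1:**
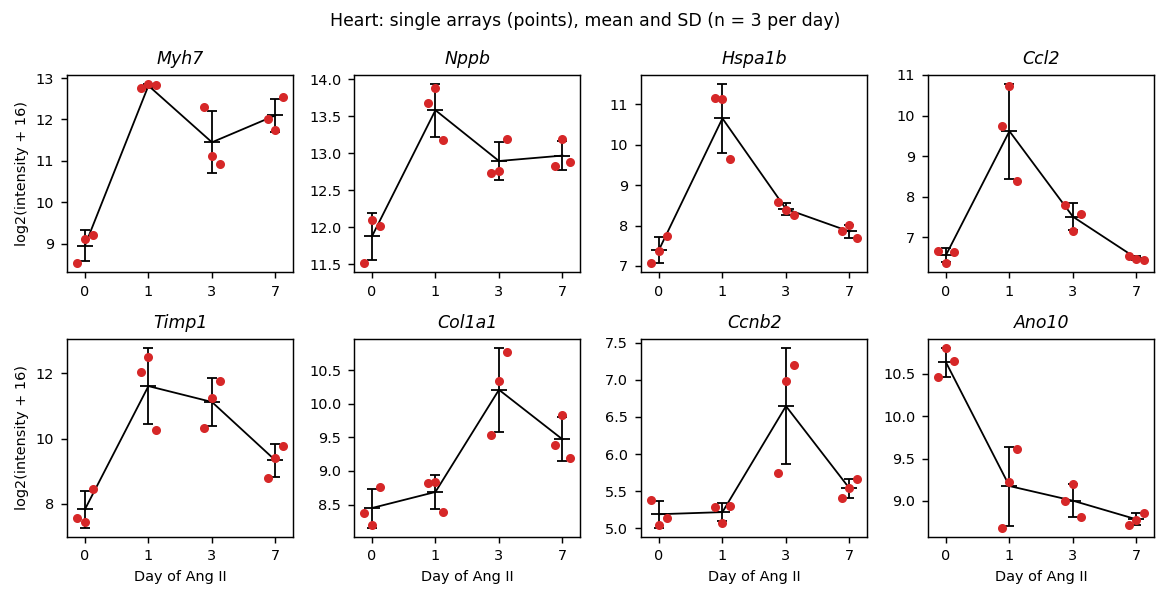
Expression of 8 genes in heart, as log2(intensity + 16) against day of angiotensin II; red points are single arrays (3 per day) and black bars the mean with its SD. Myh7 and Hspa1b stood above their day 0 values on all 3 day 1 arrays, Col1a1 and Ccnb2 had their highest mean at day 3, and Ano10 lay below its day 0 values on all 9 treated arrays.

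After 1 day, 683 heart genes rose and 1203 fell of 14040 tested, with genes of muscle stress and inflammation among the largest rises. Of these, 193 rises and 78 falls were at least 2-fold, and 3982 genes had an unadjusted p under 0.05. Myh7, the slow myosin heavy chain of the fetal ventricle, rose by 3.86 ± 0.31 on the log2 scale (SE, n = 3 against 3; 14.5-fold; adjusted p = 9.9e-05). Chil3, a chitinase-like protein of alternatively activated macrophages, rose by 5.08 ± 0.53 (adjusted p = 0.00068), and Timp1, an inhibitor of matrix metalloproteinases, by 3.78 ± 0.51 (0.0019). The other largest rises were Arg1 (3.54 ± 0.99), Nmrk2, a nicotinamide riboside kinase of muscle (3.45 ± 0.50) and S100a8 (3.40 ± 0.80). Next came the muscle ankyrin repeat gene Ankrd2 (3.35 ± 0.48), the inducible heat shock gene Hspa1b (3.26 ± 0.32), the acute phase gene Saa3 (3.20 ± 0.31) and Lcn2, lipocalin 2 (3.08 ± 0.39). The largest falls were Aplnr, the apelin receptor (-1.73 ± 0.51), Asb10 (-1.67 ± 0.27), Itih5 (-1.66 ± 0.21) and Smco1 (-1.63 ± 0.38). They also included Cmss1 (-1.56 ± 0.22), Lrrc27 (-1.54 ± 0.19), Shld1 (-1.53 ± 0.23), Tmprss13 (-1.49 ± 0.19), the sodium channel subunit Scn4b (-1.47 ± 0.16) and Ano10 (-1.46 ± 0.19). Each of these 20 genes lay on the same side of all 3 day 0 arrays on all 3 day 1 arrays, as the rule for naming them required. The other probe sets of Cmss1 changed by 0.05 and 0.03 and that of Lrrc27 by 0.12, so the falls of these genes rest on 1 probe set each.

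Of the 21 tested genes of the cardiac stress and fetal programme, 13 rose and none fell at day 1 (14 rose adjusted over the list alone). Besides Myh7, Nmrk2 and Ankrd2 they included Flnc, filamin C of the sarcomere's Z disc (2.27 ± 0.28), and Nppb, the brain natriuretic peptide gene (1.71 ± 0.20, adjusted p = 0.0012). Nppa, the atrial natriuretic peptide gene, did not pass (0.39 ± 0.14, adjusted p = 0.092). Of 28 genes of adult contraction and excitability, 5 fell and 1 rose (5 and 1 adjusted over the list alone). The falls included the potassium channel genes Kcnj3 (-1.11 ± 0.29), Kcnd2 (-1.10 ± 0.22) and Kcnip2 (-1.05 ± 0.19) and the calcium-binding Hrc (-0.59 ± 0.13). The rise was Csrp3 (0.55 ± 0.09), a gene chosen after its values were seen. Fatty acid oxidation had 5 falls and no rise among 32 genes (9 falls adjusted over the list alone). Ppargc1a, the coactivator that drives mitochondrial gene expression, fell by 1.24 ± 0.17 and its partner Ppara by 1.15 ± 0.18. Oxidative phosphorylation had 9 small falls and no rise among 46 genes (16 falls adjusted over the list alone), such as Sdhd (-0.50 ± 0.10) and Ndufa8 (-0.41 ± 0.09). Of 10 atrial markers only Clec3b passed (-0.78 ± 0.16), and of 13 adipocyte genes only the glucose transporter Slc2a4 (-0.99 ± 0.21).

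Among 34 chemokine and cytokine genes, 16 rose and none fell at day 1 (16 also adjusted over the list alone). They were led by the monocyte attractant Ccl2 (3.05 ± 0.40), Il6 (3.01 ± 0.56), Cxcl5 (2.59 ± 0.59) and Cxcl2 (2.22 ± 0.50), which attract neutrophils. Of 16 neutrophil markers, 9 rose (11 adjusted over the list alone), among them S100a9 (3.17 ± 0.87) and Clec4e (1.92 ± 0.48). Of 28 monocyte and macrophage markers, 13 rose (16 adjusted over the list alone), among them the chemokine receptor Ccr2 (2.18 ± 0.60) and Lgals3, galectin 3 (1.76 ± 0.37). T and NK cell markers had 4 rises of 13 (7 adjusted over the list alone), such as granzyme B, Gzmb (1.72 ± 0.27). B cell markers had 1 of 7 (Jchain, 1.29 ± 0.31; 1 adjusted over the list alone). No MHC class II gene of 12 passed over all genes or adjusted over the list alone in limma (list median 0.06). Red cell genes, measured as a sign of blood in the tissue, were at 0.03 ± 0.17 (Hbb-b2), 0.62 ± 0.25 (Slc4a1) and 0.34 ± 0.43 (Alas2), and none of the 3 passed over all genes or adjusted over the list alone. The arrays of day 1 differed: the neutrophil list median stood 1.62, 1.81 and 0.30 above the day 0 mean in replicates 1, 2 and 3, and the macrophage list median 0.88, 1.19 and 0.23.

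Of 22 immediate early genes 16 rose and none fell at day 1 (18 adjusted over the list alone). Socs3, which damps cytokine signalling (2.56 ± 0.42), and the transcription regulators Fos (2.34 ± 0.29), Egr1 (1.97 ± 0.28) and Btg2 (1.94 ± 0.35) led. Of 20 heat shock and folding genes 9 rose and none fell (13 rose and 1 fell adjusted over the list alone), with Hspa1a at 2.68 ± 0.32, Hspb1 at 1.25 ± 0.18 and Hsp90aa1 at 0.94 ± 0.20. Of 21 genes that respond to glucocorticoids 6 rose (10 adjusted over the list alone), including Angptl4 (2.04 ± 0.43), Cebpd (1.66 ± 0.26) and the metallothionein Mt2 (1.65 ± 0.29). The immediate early list median was 1.22, 1.50 and 0.47 in day 1 replicates 1, 2 and 3, and the heat shock median 0.42, 0.51 and 0.21. Compared with other genes by camera, the immediate early and cardiac stress lists were shifted up with a preset correlation (adjusted p = 1.7e-14 and 8.5e-14). Both had adjusted p = 0.28 with an estimated correlation, and every other heart list at day 1 had a larger p there.

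Matrix genes were mixed at day 1, with 8 rises and 4 falls among 46 (12 and 4 adjusted over the list alone). Timp1, the matrix glycoprotein tenascin C, Tnc (2.54 ± 0.65), the growth factor Ccn2 (2.48 ± 0.31) and the protease Adamts1 (1.50 ± 0.31) rose. The 4 falls, chosen after their values were seen, were Fmod (-1.02 ± 0.26), Col14a1 (-1.01 ± 0.28), Lum (-0.75 ± 0.18) and Mmp2 (-0.70 ± 0.18). In the renin-angiotensin list 4 of 13 genes fell and none rose (4 adjusted over the list alone): the peptidase Mme (-1.11 ± 0.16), Rnls (-0.69 ± 0.15), the precursor Agt (-0.55 ± 0.14) and the receptor-binding Agtrap (-0.31 ± 0.09). The angiotensin receptor Agtr1a (-0.03 ± 0.18) and Ace (0.04 ± 0.17) did not pass. Smooth muscle genes had 3 rises and 1 fall of 19 (4 and 2 adjusted over the list alone; Des 0.83 ± 0.12, Cnn1 0.78 ± 0.23, Synpo2 0.59 ± 0.12, Smtn -0.53 ± 0.13). Endothelial genes had 1 rise and 1 fall of 22 (1 and 0 adjusted over the list alone): the adhesion gene Selp rose (2.17 ± 0.47) and Aplnr fell. The remaining lists held 1 called gene each: Cenpa of 31 cell cycle genes (0.67 ± 0.12), Cmpk2 of 28 interferon genes (-1.004 ± 0.22), each also 1 adjusted over the list alone, and Per3 of 17 clock genes (-0.54 ± 0.16; 0 adjusted over the list alone).

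The count of 1886 depended on which heart was included: it was 405 without day 1 replicate 1, 623 without day 1 replicate 2 and 3441 without day 1 replicate 3. It was 574 without day 0 replicate 1, 631 without day 0 replicate 2, and 681 when the 6 arrays of the comparison were fitted alone. Of 81 called genes followed through these fits, 39 passed whichever array was left out, Myh7, Chil3, Timp1, Nppb, Hspa1b, Ccl2, Fos, Ppargc1a and Ano10 among them, while Arg1, S100a8, Aplnr and Smco1 did not. With the mean of all probe sets of a gene, Cenpa (0.14, adjusted p = 0.18), Per3 (-0.18, 0.29), Synpo2 (0.17, 0.20), Aplnr (-1.06, 0.070), Fmod (-0.62, 0.053), Col14a1 (-0.58, 0.052), Agtrap (-0.23, 0.067) and Cnn1 (0.78, 0.051) no longer passed. By the same measure Kcnip2 (-0.46), Kcnj3 (-0.57), Cmpk2 (-0.50), Tnc (1.29), Ccr2 (1.11), Angptl4 (1.04), Mme (-0.69) and Hsp90aa1 (0.61) passed with changes over 1.5 times smaller. In the joint fit Kcnip2 did not pass (adjusted p = 0.13).

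After 3 days, 10 heart genes rose and 2 fell, 9 and 1 of them by at least 2-fold, and they were mostly genes of muscle stress and matrix. Timp1 rose by 3.29 ± 0.51 (SE, n = 3 against 3; adjusted p = 0.033), Myh7 by 2.50 ± 0.31 (0.0099), the skeletal actin gene Acta1 by 1.49 ± 0.20 (0.012) and Ankrd1, a stress-induced ankyrin repeat gene of the sarcomere, by 1.28 ± 0.12 (0.0020). The collagen genes Col8a1 (2.01 ± 0.30) and Col1a1 (1.76 ± 0.27), the cartilage layer protein gene Cilp (1.80 ± 0.29) and Pcolce, which aids procollagen processing (1.02 ± 0.17), rose too. So did Mybpc2, a fast skeletal myosin-binding protein (1.07 ± 0.14), and 1700120C14Rik (0.67 ± 0.10). Ano10 (-1.63 ± 0.19, adjusted p = 0.0066) and Taf1a (-0.56 ± 0.08) fell. In each of the 12 genes all 3 day 3 arrays lay on the same side of all 3 day 0 arrays.

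Of 46 matrix genes 4 rose and none fell at day 3 over all genes, and 35 rose adjusted over the list alone. Its camera shift (adjusted p = 3.7e-31) became adjusted p = 0.28 with an estimated correlation. Cell cycle genes had 0 calls of 31 in limma over all genes and 19 rises adjusted over the list alone, and the list had adjusted p = 0.28 with an estimated correlation. The cyclins Ccna2 and Ccnb2 stood at 1.68 ± 0.33 (adjusted p = 0.075) and 1.46 ± 0.28 (0.066). The replicates differed, with matrix list medians of 0.35, 0.94 and 1.55 and cell cycle medians of 0.20, 0.70 and 1.13 above the day 0 mean in replicates 1, 2 and 3. The cardiac stress list had 3 rises of 21 (7 adjusted over the list alone). Macrophage markers had 0 calls of 28 and 10 rises adjusted over the list alone. All 28 changes were positive, with Cd68 at 1.29 ± 0.29 and Mrc1 at 0.86 ± 0.20. Adjusted over the list alone, immediate early genes had 12 rises of 22 (Nr4a1 1.18 ± 0.20, adjusted p = 0.055 over all genes) and heat shock genes 6 of 20 (Pdia6 0.78 ± 0.14, 0.065). Likewise glucocorticoid-responsive genes had 3 of 21, and neutrophil and smooth muscle genes 1 each of 16 and 19. Over all genes each of these 5 lists had 0. Of 28 interferon genes 27 had negative changes and 1 fell adjusted over the list alone (Cmpk2 -0.96 ± 0.22, adjusted p = 0.13 over all genes), with a list median of -0.45. In day 0 replicate 1 these genes stood a median of 0.99 above the other day 0 arrays, in 28 of 28 genes, and without it the median was -0.12 with 21 negative changes. No other list had a call either way. Nppb stood at 1.02 ± 0.20 (adjusted p = 0.079).

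Over all genes 1681 had an unadjusted p under 0.05 at day 3. The count of 12 was 258 without day 3 replicate 1, 4 without day 3 replicate 2, 3 without day 3 replicate 3, and 4, 1 and 4 without day 0 replicates 1, 2 and 3. It was between 7 and 25 with other filters, scales and normalization, 66 with the 6 arrays alone and 118 in the joint fit; Ankrd1 alone passed whichever array was left out.

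After 7 days, 6 heart genes rose and 1 fell, and all were at least 2-fold. Myh7 rose by 3.14 ± 0.31 (SE, n = 3 against 3; adjusted p = 0.0011), Cilp by 1.92 ± 0.29 (0.039), Acta1 by 1.67 ± 0.20 (0.0027), Mybpc2 by 1.30 ± 0.14 (0.0012), Ankrd1 by 1.28 ± 0.12 (0.0011) and Depp1, a FOXO-regulated gene of autophagy, by 1.19 ± 0.13 (0.0012). Ano10 fell by 1.85 ± 0.19 (0.0011). All 3 day 7 arrays lay on the same side of all 3 day 0 arrays for each. Matrix genes had 1 rise of 46 over all genes and 22 adjusted over the list alone, with 45 of 46 changes positive, a median of 0.64 and adjusted p = 0.28 with an estimated correlation. The cardiac stress list had 3 rises of 21 (6 adjusted over the list alone), and Nppb was at 1.09 ± 0.20 (adjusted p = 0.12). Adjusted over the list alone, 6 of 21 glucocorticoid-responsive genes rose (Sgk1 0.71 ± 0.16 and Cebpd 1.04 ± 0.26) and 5 of 22 immediate early genes (Fos 1.28 ± 0.29), with 0 over all genes. By the same count 1 gene each fell in the fatty acid oxidation and clock lists, and no other list had a call either way. Over all genes 1247 had an unadjusted p under 0.05. The count of 7 was 173 with the 6 arrays alone and 21 in the joint fit, and each of the 7 except Cilp passed whichever array was left out.

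**Figure D2:**
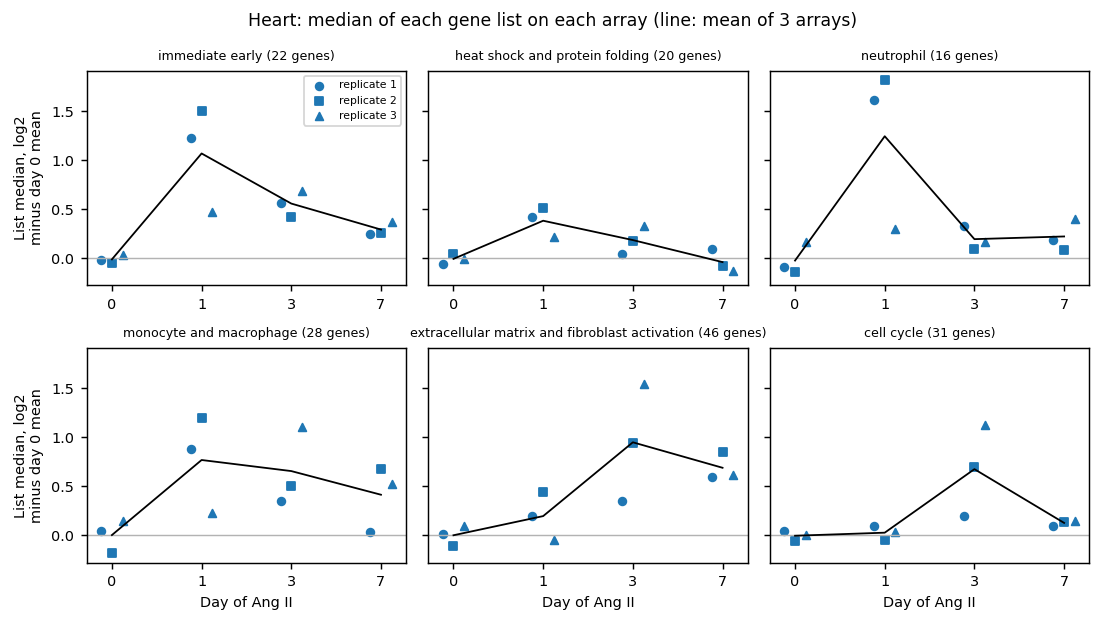
Median of 6 gene lists on each heart array, as log2 difference from the mean of the 3 day 0 arrays, against day of angiotensin II; symbols are replicates and lines the mean of 3 arrays. Neutrophil and immediate early medians were highest in day 1 replicates 1 and 2, and matrix and cell cycle medians in day 3 replicate 3.

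Between day 1 and day 3, 397 heart genes rose and 207 fell (604 of 14040), but this count rests on single arrays. It was 0 without day 3 replicate 2, 0 with the 6 arrays alone, 9 without day 1 replicate 1, 103 without day 1 replicate 2 and 250 without day 3 replicate 3. The largest rises were matrix genes of activated fibroblasts, Cthrc1 (2.66 ± 0.66; SE, n = 3 against 3; adjusted p = 0.042), asporin, Aspn (2.53 ± 0.35, 0.0090), Cilp (2.16 ± 0.29, 0.0088) and periostin, Postn (2.12 ± 0.41, 0.017), then 2210407C18Rik (1.94 ± 0.36). The largest falls were Chil3 (-2.91 ± 0.53, 0.016), Ankrd2 (-2.32 ± 0.48, 0.020), Saa3 (-2.25 ± 0.31, 0.0090), Hspa1b (-2.24 ± 0.32, 0.0090) and Hspa1a (-2.15 ± 0.32, 0.0097). Of 46 matrix genes 15 rose and none fell (23 rose and 2 fell adjusted over the list alone), and of 31 cell cycle genes 14 rose and none fell (19 and 1 adjusted over the list alone). Col1a1 rose by 1.52 ± 0.27 and the proliferation marker Mki67 by 1.71 ± 0.44. The cardiac stress list had 8 falls and 1 rise of 21 (11 and 1 adjusted over the list alone). Chemokines had 6 falls of 34 (14 adjusted over the list alone; Ccl2 -2.10 ± 0.40) and heat shock genes 4 of 20 (7 falls and 1 rise adjusted over the list alone). Neutrophil markers had 3 of 16 (7 adjusted over the list alone) and T and NK cell markers 2 of 13 (6 adjusted over the list alone; Gzmb -2.13 ± 0.27). Another 11 lists had 1 to 3 calls each. They included immediate early genes (1 fall of 22; 1 rise and 11 falls adjusted over the list alone), the renin-angiotensin list (1 rise of 13; 4 adjusted over the list alone) and fatty acid oxidation (2 rises and 1 fall of 32, also adjusted over the list alone). Ccl2, Gzmb, Col1a1 and Mki67 here are examples chosen after their values were seen. With an estimated correlation every list had an adjusted p of at least 0.56. The count was 2049 without day 1 replicate 3, 351 with a replicate block and 987 in the joint fit, and none of 29 called genes followed passed whichever array was left out.

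Between day 3 and day 7 no heart gene was called by limma, and 983 had an unadjusted p under 0.05. The smallest p belonged to genes of protein folding in the endoplasmic reticulum, Pdia6 (-0.94 ± 0.14; SE, n = 3 against 3; adjusted p = 0.24) and Sdf2l1 (-1.20 ± 0.21, 0.52), then Depp1 (0.65 ± 0.13, 0.61). Of 31 cell cycle genes 30 had negative changes, 0 were called over all genes and 21 fell adjusted over the list alone (median -0.53; adjusted p = 0.56 with an estimated correlation). Adjusted over the list alone, 4 heat shock genes and 1 matrix gene fell and 2 glucocorticoid-responsive genes and 1 chemokine rose, all 0 over all genes. All 28 interferon genes had positive changes, with 0 called either way. The count was 63 without day 3 replicate 1, 4 without day 7 replicate 1, 2 in the joint fit and 1 with the 6 arrays alone.

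In kidney after 1 day, 37 genes rose and 34 fell of 14214 tested, 16 and 11 of them by at least 2-fold. Transporters and enzymes of the proximal tubule were among the falls. Cyp4a14, a fatty acid hydroxylase induced through PPAR alpha, rose by 2.70 ± 0.22 (SE, n = 2 against 2; 6.5-fold; adjusted p = 0.010), Bbox1, the last enzyme of carnitine synthesis, by 1.98 ± 0.16 (0.0098). The cholesterol transport genes Apoe and Abca1 rose by 1.85 ± 0.22 (0.030) and 1.55 ± 0.20 (0.037). Ceruloplasmin, Cp (2.03 ± 0.27), 2410006H16Rik (1.81 ± 0.10), 1110038B12Rik (1.38 ± 0.11), Aldh1a7 (1.30 ± 0.19) and the small nucleolar RNA host genes Snhg12 (1.48 ± 0.12) and Zfas1 (1.27 ± 0.11) also rose. The amino acid transporter Slc7a13 fell by 2.12 ± 0.15 (0.0098), as did the organic anion transporters Slc22a30 (-1.99 ± 0.28) and Slc22a19 (-1.24 ± 0.18), and the brush border protease Mep1b (-1.62 ± 0.19). Further falls were the steroid transporter subunit Slc51a (-1.39 ± 0.13), Bcat1 (-1.51 ± 0.16), Acy3 (-1.32 ± 0.17), Mpv17l (-1.15 ± 0.15) and the sterol synthesis enzymes Idi1 (-1.84 ± 0.20) and Cyp51 (-1.14 ± 0.16). Both day 1 arrays lay on the same side of both day 0 arrays for each of these 20, as the rule for naming them required. Markers of other organs moved on the same arrays: the liver marker median stood 5.62 above day 0 in day 1 replicate 2 (0.28 in replicate 1), and the adipocyte list median 1.62 and 1.89 above in replicates 1 and 2.

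Of 31 proximal tubule genes 2 fell and none rose (11 fell adjusted over the list alone): Slc7a13 and the phosphate transporter Slc34a1 (-0.64 ± 0.09). The list had adjusted p = 0.41 with an estimated correlation. Of 22 kidney injury genes 2 rose (6 adjusted over the list alone; adjusted p = 0.25 with an estimated correlation): Cp, which liver also makes, and the keratin Krt18 (0.80 ± 0.10). The list holds fibrinogen genes that liver makes too, and the liver marker Alb stood at 13.6 in day 1 replicate 2 and 6.6 in replicate 1 on the log2 scale. Glucocorticoid-responsive genes had 2 rises of 22 (9 adjusted over the list alone), the metallothioneins Mt2 (1.08 ± 0.16) and Mt1 (0.72 ± 0.11). Immediate early genes had 1 of 20 (11 adjusted over the list alone; Ccn1 1.17 ± 0.17), and matrix genes 1 of 43 (5 rises and 1 fall adjusted over the list alone; Adamts1 0.58 ± 0.08). With 0 calls over all genes, fatty acid oxidation had 6 rises of 32 adjusted over the list alone (Eci1 0.98 ± 0.16, adjusted p = 0.059) and neutrophil markers 4 of 14 (S100a8 2.19 ± 0.35, 0.059). The renin-angiotensin list had 1 rise and 4 falls of 13 (Ace -0.83 ± 0.21, 0.13; Agtr1a -0.32 ± 0.10, 0.21). Likewise heat shock genes had 2 rises of 20, endothelial genes 2 rises and 1 fall of 22, distal nephron genes 1 and 1 of 29, and macrophage markers 1 fall of 27 adjusted over the list alone. The adipocyte list had a median of 1.76 with 0 of 15 called and the adrenal list -0.73 with 0 of 10 called, and no other list had a call either way.

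Over all genes 2311 had an unadjusted p under 0.05 in kidney at day 1. The count of 71 was 0 without day 0 replicate 1, 8 without day 0 replicate 2, 147 without day 1 replicate 1, 27 without day 1 replicate 2. It was 34 without the arrays that carried adrenal markers, 0 with the adipocyte median as a covariate, between 20 and 31 without a filter, with a replicate block or with an added value of 1, 146 with trended variances and 235 in the joint fit. Cp, Abca1, Aldh1a7, Bcat1 and Slc51a were among the genes that did not pass without day 1 replicate 2, and Cyp4a14, Bbox1, Apoe, Slc7a13, Idi1 and Snhg12 among those that did. With the mean of all probe sets of a gene, Abca1 (0.68), Bcat1 (-0.67) and Mt1 (0.36) did not pass, and Slc7a13 (-1.13) and Ccn1 (0.57) passed with smaller changes.

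**Figure D3:**
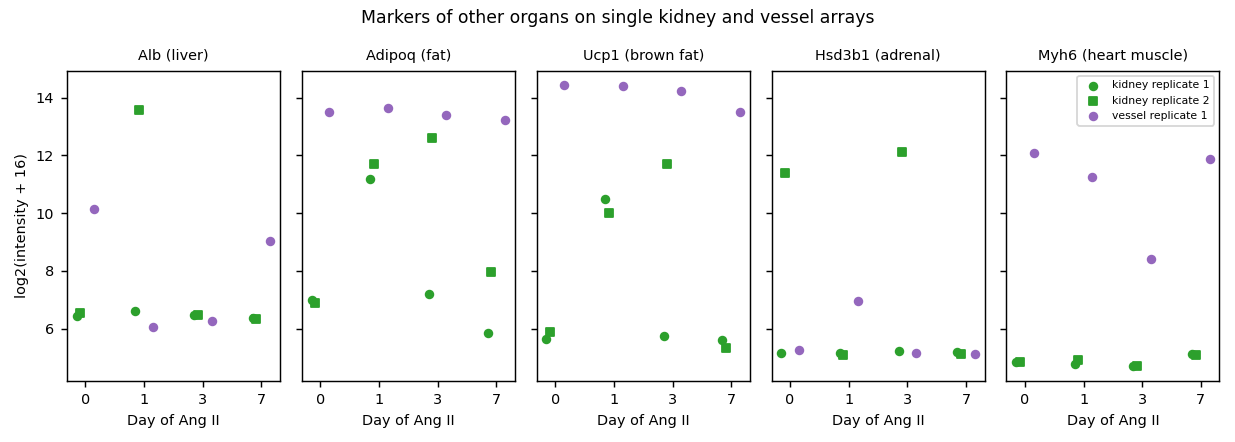
Marker genes of liver, fat, brown fat, adrenal cortex and heart muscle on single kidney (green) and vessel (purple) arrays, as log2(intensity + 16) against day of angiotensin II. Alb reached 13.6 on 1 kidney array of day 1, Adipoq exceeded 11 on both day 1 arrays and 1 day 3 array, and Hsd3b1 exceeded 11 on 1 array each of days 0 and 3.

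In kidney after 3 days no gene was called by limma, and 1202 had an unadjusted p under 0.05. The smallest p were those of the death ligand gene Tnfsf10 (-0.90 ± 0.09; SE, n = 2 against 2; adjusted p = 0.19), Tmem237 (-0.70 ± 0.09, 0.26) and Slc51a (-0.9999 ± 0.13, 0.26). Adjusted over the list alone, 3 of 31 proximal tubule genes fell (Cyp7b1 -1.34 ± 0.19), 2 of 9 podocyte genes rose (Ptpro 0.65 ± 0.13, Podxl 0.57 ± 0.13), and 2 of 29 distal nephron genes rose (Slc26a4 0.42 ± 0.08 and the sodium channel subunit Scnn1g 0.47 ± 0.09). Single genes passed that way in the kidney injury, glucocorticoid, smooth muscle, interferon and renin-angiotensin lists. All 8 lists had 0 over all genes. The interferon list median was -0.58, with 27 of 28 changes negative. Day 0 replicate 1 stood a median of 0.81 above replicate 2 in that list, and without it the median was -0.17 with 22 changes negative. Day 3 replicate 2 carried fat and adrenal markers, with list medians 3.20 and 2.12 above day 0. The count was 4 without day 0 replicate 2, 68 without day 3 replicate 1 and 25 in the joint fit.

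In kidney after 7 days no gene was called by limma, and 950 had an unadjusted p under 0.05. The smallest p belonged to the macrophage and epithelial galectin Lgals3 (0.95 ± 0.12; SE, n = 2 against 2), Olfml3 (-0.56 ± 0.08) and Sema3g (1.11 ± 0.16), each with adjusted p = 0.60. With 0 calls over all genes, 3 of 22 kidney injury genes (Krt18 0.40 ± 0.10, Tnfrsf12a 0.62 ± 0.16), 2 of 14 neutrophil markers (S100a9 1.60 ± 0.34, S100a8 1.51 ± 0.35), and 2 of 20 immediate early genes (Ccn1 0.84 ± 0.17, Fos 1.50 ± 0.36) rose adjusted over the list alone. So did 2 of 43 matrix genes, 1 of 27 macrophage markers and 1 of 9 podocyte genes, and 2 of 29 distal nephron genes rose and 1 fell. Of 27 macrophage markers 25 had positive changes, with a median of 0.46. The joint fit called 7 genes.

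In brain, no gene was called by limma at day 3 or day 7, and 1041 and 1006 of 14109 had an unadjusted p under 0.05. At day 3 the smallest p were those of Hp, haptoglobin (-1.08 ± 0.12; SE, n = 2 against 2), Kl, klotho, which the choroid plexus makes in quantity (-1.85 ± 0.20), and Rgs17 (0.92 ± 0.12), each with adjusted p = 0.66. All 13 choroid plexus genes had negative changes at day 3, with a median of -1.77, and 10 fell adjusted over the list alone (0 over all genes; F5 -2.14 ± 0.39). Cerebellar genes had a median of -2.37 with 0 of 14 called either way. Of 18 glial genes 3, Cd44 (-0.84 ± 0.16) and Vim (-0.85 ± 0.17) among them, and 1 gene each of the neutrophil and MHC class II lists fell adjusted over the list alone. Transthyretin, Ttr, the most abundant choroid plexus product, stood at 14.3 and 14.2 on the day 0 arrays and 6.6 and 11.05 on the day 3 arrays. The replicates of a day differed in their cerebellar medians by up to 2.04. The microglia median was 0.28, with all 18 changes positive, and the striatum, neuron and oligodendrocyte medians were 0.54, 0.16 and 0.10, with 0 called either way. The count was 400 in the joint fit at day 3.

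At day 7 the smallest p in brain were those of Irs4 (2.00 ± 0.20; SE, n = 2 against 2), the calcitonin receptor gene Calcr (0.98 ± 0.10) and Fam183b (1.10 ± 0.12), each with adjusted p = 0.56. Hypothalamic and pituitary genes had 5 rises of 18 adjusted over the list alone (0 over all genes), among them the orexin gene Hcrt (1.76 ± 0.30) and Pomc (1.21 ± 0.18), with adjusted p = 0.56 with an estimated correlation. Pmch, a peptide gene of the lateral hypothalamus, stood at 5.3 and 5.6 at day 0, 10.2 and 5.4 at day 3 and 11.2 and 11.1 at day 7. Choroid plexus genes had 2 falls of 13 adjusted over the list alone (0 over all genes; Kl -1.13 ± 0.20) and a median of -0.91. Adjusted over the list alone, 2 MHC class II genes and 1 gene each of the neutrophil and erythroid lists fell and 1 B cell gene rose (0 over all genes). Striatum, microglia, neuron and oligodendrocyte medians were 0.75, 0.22, 0.14 and 0.08 and the cerebellar median -1.33, with 0 called either way. The activity-induced genes Arc (1.13 ± 0.30) and Npas4 (1.36 ± 0.25) did not pass (adjusted p = 0.67). The count was 168 in the joint fit and 1 with the 4 arrays alone.

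Whether heart and kidney differed in their response was tested as the change in heart minus the change in kidney. A gene was included when it passed the filter in either tissue. For genes hardly expressed in the other tissue, such as genes of muscle in kidney, the difference mainly repeats the change in the first. At day 1 the difference passed for 501 of 14715 genes, 140 higher and 361 lower in heart. It was largest for Chil3 (4.20 ± 1.03 on the log2 scale; SE, n = 3 and 2 per group; adjusted p = 0.031), Myh7 (3.62 ± 0.57, 0.0026), Nmrk2 (3.56 ± 0.66, 0.0070), Ankrd2 (3.37 ± 0.62, 0.0070) and Timp1 (3.18 ± 0.76, 0.028). On the other side stood the fat genes Adipoq (-5.12 ± 1.35, 0.044) and Cidea (-4.33 ± 1.16, 0.046), Thrsp (-3.63 ± 0.92, 0.037; -1.95 and 0.059 with the mean of its probe sets). The fibrinogen genes Fgg (-3.62 ± 0.60, 0.0038) and Fga (-3.16 ± 0.59, 0.0070) joined them, and the day 1 kidney arrays had the fat and liver markers given above. Chemokines had 5 of 34 genes higher in heart (Ccl2 3.03 ± 0.57, Il6 3.04 ± 0.74), heat shock genes 4 of 20 (Hspa1b 2.49 ± 0.55) and macrophage markers 2 of 28. In turn 4 of 32 fatty acid oxidation genes (Ppara -1.43 ± 0.30, Ppargc1a -1.16 ± 0.25) and 5 of 15 adipocyte genes were lower. T and NK cell and smooth muscle genes had 1 higher each and matrix genes 1 higher and 1 lower, and no immediate early or glucocorticoid-responsive gene differed. The members named here for lists were chosen after their values were seen. By camera with the preset correlation, adjusted p was smallest for chemokines (3.5e-07, higher in heart), fatty acid oxidation (7.3e-07, lower) and macrophage markers (1.4e-06, higher). With an estimated correlation every list had an adjusted p of at least 0.62. The count of 501 was 183, 266 and 1695 without day 1 heart replicates 1, 2 and 3, and 215 and 230 without day 0 heart replicates 1 and 2. It was 260 and 137 without day 0 kidney replicates 1 and 2, 325 and 186 without day 1 kidney replicates 1 and 2, and 258 with a replicate block. Of 21 called genes followed, 7 passed whichever array was left out (Myh7, Nmrk2, Ankrd2, Ccl2, Nppb, Fgg and Fga), and Chil3, Timp1, Adipoq and Cidea did not.

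At day 3, 8 genes differed between heart and kidney: Ankrd1 (1.16 ± 0.20), Mybpc2 (1.08 ± 0.19), Lipo3 (1.05 ± 0.18), Slc22a19 (1.01 ± 0.17) and Slc51a (0.93 ± 0.17) changed more positively in heart. Ano10 (-1.62 ± 0.27), Cyp4a14 (-1.57 ± 0.20) and the epithelial Eppk1 (-1.04 ± 0.18) changed more negatively. Adjusted p was 0.0028 for Cyp4a14 and 0.041 for the rest. At day 7, 4 genes differed: Acta1 (1.79 ± 0.30, adjusted p = 0.043), Mybpc2 (1.27 ± 0.19, 0.013), Ano10 (-1.80 ± 0.27, 0.013) and Cyp4a14 (-1.40 ± 0.20, 0.013). The day 3 count was between 1 and 3 without each of the day 0 or day 3 arrays except 99 without heart day 3 replicate 1 and 89 without kidney day 3 replicate 1. It was 0 with a replicate block, 1 with an added value of 1 and 34 with 64, and only Cyp4a14 passed whichever array was left out. The day 7 count was 0 without kidney day 0 replicate 1, 0 without kidney day 7 replicate 1 and 0 with a replicate block. It was 2 to 7 with other scales and probe set rules.

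In the joint fit heart and brain differed in 108 of 14959 genes at day 3, 70 higher and 38 lower in heart. That fit gave all tissues a single estimate of spread per gene. Brain replicates differed more, with correlations of 0.9665 to 0.9908 against 0.9808 to 0.9962 in heart. The adjusted p of genes that vary mainly in brain may therefore be too small, and brain fitted alone had no call. Genes hardly expressed in heart show mainly the change in brain. The largest positive differences were those of Tnc (4.50 ± 0.87, SE, n = 3 and 2 per group, adjusted p = 0.023, 2.32 with the mean of its probe sets), Timp1 (3.39 ± 0.76, 0.043), Crtam (3.09 ± 0.67), Ppp1r17 (2.61 ± 0.58) and Fam107b (2.59 ± 0.57). The largest negative differences were those of Cmpk2 (-1.47 ± 0.32), Ano10 (-1.45 ± 0.27), Grp (-1.36 ± 0.19), Dcaf12l1 (-1.35 ± 0.31) and Gng4 (-1.33 ± 0.28). A difference can come from a change in either tissue, and of these genes only Timp1 and Ano10 were called in heart itself at day 3. Matrix genes had 4 of 46 higher in heart and cell cycle genes 2 of 32. By camera their adjusted p was 1.7e-17 and 4.3e-14 with the preset correlation and 0.62 for both with an estimated correlation. Single immediate early and heat shock genes were higher and 1 interferon gene lower. The choroid plexus genes Kl and Kcne2, chosen after their values were seen, stood 1.92 ± 0.23 and 2.32 ± 0.35 higher in the difference, beside brain arrays whose Ttr ranged from 6.6 to 14.3. At day 7, 50 genes differed, 12 higher and 38 lower in heart. Acta1 (1.77 ± 0.30), Kcne2 (1.66 ± 0.35), Ankrd1 (1.34 ± 0.20), Mybpc2 (1.34 ± 0.19) and St8sia5 (1.10 ± 0.23) were highest. The lowest were the hypothalamic peptide genes Pmch (-5.72 ± 1.02), Oxt, oxytocin (-2.45 ± 0.43), Grp (-1.85 ± 0.19) and Hcrt (-1.82 ± 0.26), and Irs4 (-2.02 ± 0.16, adjusted p = 1.4e-06). At day 3 the count was 45 and 1293 without day 0 brain replicates 1 and 2, 179 without day 3 brain replicate 2, and 34, 38 and 39 without day 0 heart replicates 1, 2 and 3. It was 303, 35 and 50 without day 3 heart replicates 1, 2 and 3, and 50 with an added value of 1. At day 7 it was 985 without day 0 brain replicate 2, 140 and 24 without day 7 brain replicates 1 and 2, and 32, 30 and 31 without heart day 0 replicates 1 and 2 and day 7 replicate 3, and 85 with an added value of 64. Whichever array was left out, Ano10, Grp, Kl, Kcne2 and Col8a1 passed of 14 genes followed at day 3 (Col8a1 chosen after its values were seen), and Acta1, Ankrd1, Mybpc2, Grp, Hcrt and Irs4 of 10 at day 7.

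In vessel, with a single array per time and so no replicate check and no test, macrophage genes stood above day 0 at all 3 times and matrix and cell cycle genes at days 3 and 7. Of 14295 genes, 93 were at least 2-fold higher and 108 lower at day 1, 684 and 185 at day 3, and 590 and 175 at day 7. At all 3 times 30 were higher and 27 lower. The genes highest at all times were Lcn2 (3.11, 3.38 and 3.67 on the log2 scale at days 1, 3 and 7), Chil3 (2.24, 2.70, 2.77), the protease inhibitor Serpina3n (2.23, 3.02, 3.13), the chemokine Ccl12 (1.79, 2.67, 2.41) and Ifitm1 (1.78, 2.54, 1.70). Next were Aif1, a macrophage gene (1.69, 3.15, 1.68), Ms4a6b (1.66, 3.29, 2.72), Saa3 (1.91, 3.08, 1.65), S100a8 (2.08, 1.62, 1.53) and Hp (1.59, 1.50, 2.08). The lowest were genes of liver secretion and urea synthesis, such as Serpina1c (-4.45, -4.38, -1.49), Fgb (-2.50, -2.49, -1.92), Apoc3 (-1.86, -1.80, -1.41) and Cps1 (-1.99, -2.10, -1.26), and the muscle gene Hrc (-1.31, -2.00, -1.42). Alb itself stood at 10.2, 6.1, 6.3 and 9.0 at days 0, 1, 3 and 7, the heart muscle gene Myh6 at 12.1, 11.2, 8.4 and 11.9, and the brown fat gene Ucp1 at 14.4, 14.4, 14.2 and 13.5.

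The 28 macrophage markers in vessel had medians of 0.57, 1.94 and 1.33 at days 1, 3 and 7, above all 10000 random lists matched on expression, with Fcgr1 at 1.31, 3.01 and 1.87. Ranks among random lists here are descriptions and not tests. Random lists do not keep the correlation among genes of a list. With single arrays, the ranks cannot part a response from differences in cell or organ content between samples. Interferon genes had medians of 0.82, 1.39 and 0.32 (Ifit1 1.47, 2.48, 0.98), MHC class II genes 0.26, 1.43 and 0.12 (Cd74 0.18, 1.56, 0.37). Chemokines stood at 0.17, 0.67 and 0.33 (Ccl8 1.29, 3.76, 2.44) and neutrophil markers 0.59, 0.64 and 0.63. The 46 matrix genes had a median of -0.31 at day 1, below every random list, then 1.26 and 1.12, above every random list (Timp1 0.96, 4.07, 4.20; Tnc 0.45, 2.21, 2.37). Cell cycle genes went from 0.03 to 0.84 and 1.30 (Mcm5 0.26, 1.28, 2.19). Contractile smooth muscle genes had medians of -0.64, -0.38 and -0.30, with Myh11, the smooth muscle myosin, at -0.83, -0.87 and -1.02. Glucocorticoid-responsive (0.39, 0.59, 0.66), immediate early (0.21, 0.57, 0.62) and heat shock genes (0.09, 0.16, 0.32) had positive medians at each time, and adipocyte genes stood at 0.07, -0.21 and -0.37. The endothelial median was -0.05, -0.07 and 0.02, although Esm1, a marker of activated endothelium, stood at 0.51, 1.83 and 3.15 and the adhesion gene Vcam1 at 0.46, 1.99 and 1.77. T and NK cell (0.35, 0.13, 0.04), B cell (0.02, 0.52, 0.05), renin-angiotensin (0.08, 0.25, 0.04), clock (-0.00, -0.20, -0.04) and skeletal muscle genes (-0.08, -0.27, -0.12) had these medians, and 3 erythroid genes 0.67, 0.89 and 1.52. With the mean of all probe sets of a gene, days 3 and 7 stood at 1.81 and 0.94 for Fcgr1, 1.10 and 1.19 for Tnc, 0.52 and 1.03 for Mcm5, 1.34 and 1.14 for Vcam1 and -0.78 and -0.52 for Myh11. By that measure the cell cycle median was 0.54 at day 3 and 1.09 at day 7, and the MHC class II median 0.09, 1.01 and 0.04 at days 1, 3 and 7. The day 7 array had a Gapdh 3' minus 5' difference of 0.92 on the log2 scale, against 0.23 to 0.28 on the other vessel arrays.

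**Figure D4:**
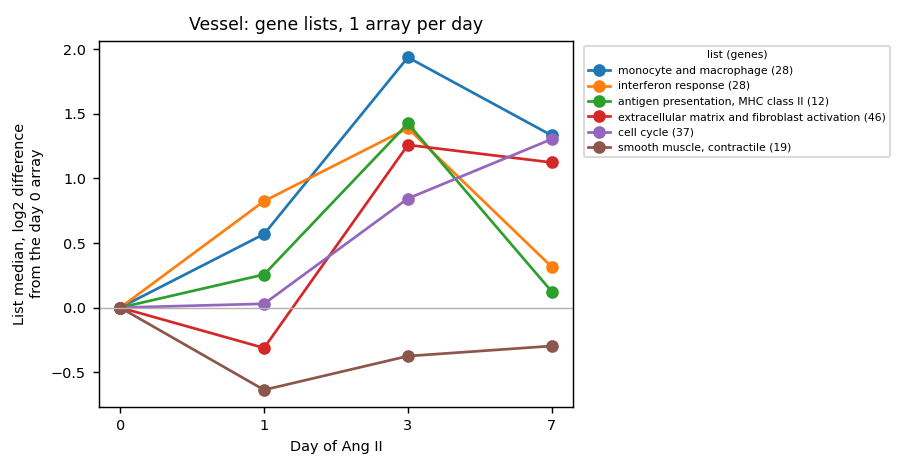
Medians of 6 gene lists in vessel, as log2 difference from the day 0 array, against day of angiotensin II; each point is a single array. Macrophage, interferon, MHC class II and matrix medians were highest at day 3, the cell cycle median at day 7, and the smooth muscle median lay below 0 at all 3 times.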

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

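The tests of other organs' RNA, blood, pump and handling, and brain regions below were chosen only after the result was seen, while the splits of the heart arrays were planned. Most of these results are listed because the change differed between tissues by a test of the difference itself. That test used a single spread per gene for all tissues and included genes that passed the filter in either tissue.

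Between heart and kidney the difference passed for 501 genes at day 1, among them Chil3 (4.20) and Myh7 (3.62) with a higher change in heart and Adipoq (-5.12) and Cidea (-4.33) with a lower change. Of these 4 only Myh7 passed whichever array was left out. At day 3 it passed for 8 genes, among them Ankrd1 (1.16), Mybpc2 (1.08), Ano10 (-1.62) and Cyp4a14 (-1.57). At day 7 it passed for 4 genes: Acta1 (1.79), Mybpc2 (1.27), Ano10 (-1.80) and Cyp4a14 (-1.40). With a replicate block no gene passed between heart and kidney at day 3 or day 7. Between heart and brain it passed for 108 genes at day 3, with Tnc (4.50), Timp1 (3.39), Cmpk2 (-1.47) and Ano10 (-1.45) among them, and for 50 at day 7, with Acta1 (1.77), Kcne2 (1.66), Pmch (-5.72) and Oxt (-2.45). Adipoq and Cidea are fat genes, and Kcne2, Pmch and Oxt are genes of single brain regions.

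Outside the genes tested, 45 of 4116 bright probe sets without a single gene symbol were higher and 49 lower in heart at day 1 (adjusted over those probe sets by limma).

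Kidney day 1 arrays carried RNA of other organs beside their 71 called genes. Liver markers stood 5.62 above day 0 in replicate 2 and 0.28 in replicate 1. With replicate 2 left out, 20 of the 71 genes were still called, and the other 51 had a median change of 0.85 (SE 0.14) against 0.85 (SE 0.11) with it, their calls ending because fewer arrays widen the error. The called genes changed alike in both replicates (median 0.94 in replicate 1 and 0.90 in replicate 2). With 2 arrays per day, a gene raised by liver RNA in replicate 2 alone could hardly be called. The refit therefore cannot decide on liver RNA as a source of change. Fat markers stood 1.62 and 1.89 above day 0 in both replicates. With the adipocyte median as a covariate the genes called higher had a median change of 1.01 (SE 0.14) against 0.94 (SE 0.11) without it. Within a day the covariate varied mainly at day 3 (0.14 in replicate 1, 3.20 in replicate 2). There the genes called higher stood at 0.31 in both replicates. Calls favour genes with little spread within a day, so the covariate could hardly lower their change and cannot decide on fat. With the covariate 0 genes were called, since it parts both day 1 arrays from both day 0 arrays and leaves 3 residual degrees of freedom. Adipoq itself went from 4.52 to 0.96. A kidney response to angiotensin II stays open, untested, as do RNA of liver or fat and dissection differences that moved other tissues.

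The heart at day 1 had a burst of leukocyte, immediate early and heat shock genes. More blood left in the day 1 hearts would raise red cell genes by about as much as the neutrophil median of 1.28. Of 3 red cell markers, 2 had an upper 95% limit below that: Hbb-b2 (0.03, limit 0.41) and Slc4a1 (0.62, limit 1.20), while that of Alas2 (0.34, limit 1.35) was above it, so more blood stays open. These limits used the 8 residual degrees of freedom without those added by moderation, so they are somewhat wide, and that of Alas2 lies close to the neutrophil median. Pump implantation and handling could raise the same stress genes: 3 of 62 members of the glucocorticoid, immediate early and heat shock lists were called higher in kidney, against 31 of 63 in heart, with medians of 0.49 and 0.54. Angiotensin II and surgery cannot be told apart here for these genes, because the labels name no group with a pump and no angiotensin II.

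Markers of brain regions differed between arrays of the same day. For 4 of 4 region lists (cerebellum, choroid plexus, hypothalamus and pituitary, striatum) the gap between replicates of a day was at least 0.5 times the largest difference between day means, which different parts of the brain in single samples may explain. The cerebellar gap was 2.04 against 2.40 between day means, and the striatal gap 1.92 against 0.67. That of choroid plexus was 0.84 against 1.53, and that of hypothalamus and pituitary 0.44 against 0.74. Only in striatum was the gap larger than the difference between day means. A change in these genes under angiotensin II stays open, untested.

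For heart, other splits of the 6 arrays of each comparison were fitted, 10 in all for each, which is too few for a share under 0.05. The real split gave 1886 genes at day 1 (1 of 10 splits gave as many, highest other 1), 12 at day 3 (1 of 10, highest other 0) and 7 at day 7 (1 of 10, highest other 0). Day 7 against day 3 gave 0 in all 10. For day 3 against day 1, 2 of 10 splits gave as many: the real split 604 and another 631, which set day 1 replicates 1 and 2 and day 3 replicate 3 against day 1 replicate 3 and day 3 replicates 1 and 2. That split points to a structure of the samples across days, with the arrays of larger list medians of each day on the same side. For the test of any time, 1 of 100 drawn splits of the 12 arrays gave as many as the real 920, with 318 the highest other. The real split is that 1 of the 100, so chance is unlikely as the source of this count but not excluded.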

How the results depend on the processing

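The fits without adrenal-marker arrays, with an adipocyte covariate and with day and number as a correlated block were tests chosen only after the result was seen. Of 4722 alternative values of 307 named gene results, 3695 kept their side of the threshold, 975 no longer passed and 52 newly passed. Where the main or the alternative fit passed, 0 changed sign. The 307 include results that did not pass in the main fit, which count as kept when they again did not pass. Among all called genes, 3 of those called in heart at day 1 had the opposite sign with the mean of all probe sets. Leaving out 1 array accounts for 595 of the 975. Counts that moved by over 1.5 times follow, and the cause was not tested except where fewer samples or residual degrees of freedom show it.

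No filter: heart day 3 7, kidney day 1 20. Quantile normalization again: heart day 3 25. Mean of all probe sets: heart day 3 7, heart minus kidney day 7 7. Trended and robust variances: kidney day 1 146. Added value 1: kidney day 1 31, heart minus kidney day 3 1 and day 7 2, heart minus brain day 3 50. Added value 64: heart day 3 7, heart minus kidney day 3 34 and day 7 7, heart minus brain day 7 85. Joint fit: heart day 3 118, day 7 21, day 3 against day 1 987, day 7 against day 3 2, any time 1680, kidney day 1 235, day 3 25, day 7 7, brain day 3 400, day 7 168. Only the groups compared: heart day 1 681, day 3 66, day 7 173, day 3 against day 1 0, day 7 against day 3 1, brain day 7 1. Without adrenal-marker arrays: kidney day 1 34. Adipocyte covariate: kidney day 1 0.

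Replicate block: heart day 3 7, day 3 against day 1 351, any time 455, kidney day 1 21, heart minus kidney day 1 258, day 3 0, day 7 0. Arrays with the same replicate number correlated, after removal of group means, at -0.33 to 0.15 in heart (2 of 18 above 0.1), -0.09 to 0.24 in kidney (median 0.15, 8 of 12 above 0.1) and -0.64 to 0.48 in brain (2 of 6). With 2 arrays per day in kidney and brain, removal of the day mean gives replicates 1 and 2 the same correlation, so each value is counted 2 times. Not every pair passed 0.1, which does not show that arrays of the same number share nothing else. Between heart and kidney they correlated at 0.03 to 0.24 (5 of 8 above 0.1), between heart and brain at -0.08 to 0.12 and between kidney and brain at 0.04 to 0.08. The labels do not say whether organs of the same day and number came from the same mouse. With day and number as a correlated block (limma, correlation 0.054), heart minus kidney had 691, 8 and 4 genes at days 1, 3 and 7 and heart minus brain 145 and 61 at days 3 and 7.

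With each array left out in turn, lowest and highest counts were: heart day 1 405 and 3441, day 3 1 and 258, day 7 6 and 8, any time 51 and 2671, day 3 against day 1 0 and 2049, day 7 against day 3 0 and 63; kidney day 1 0 and 147, day 3 0 and 68, day 7 0 and 0; brain 0 and 0 at both days; heart minus kidney day 1 137 and 1695, day 3 1 and 99, day 7 0 and 5; heart minus brain day 3 34 and 1293, day 7 24 and 985. The highest heart day 1 and day 3 counts came without day 1 replicate 3 and day 3 replicate 1.

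In vessel, genes at least 2-fold higher and lower at days 1, 3 and 7 numbered 77 and 68, 493 and 141, and 392 and 128 with the mean of probe sets, and 87 and 118, 638 and 217, and 516 and 220 with quantile normalization again. In simulated data, 2-fold changes were recovered for between 91.0 and 98.5% of genes in heart and kidney, 40.3 and 41.8% in brain, and 68.7 to 73.1% for tissue differences, with 4 to 12 unchanged genes called. The simulated noise was independent between genes, without differences between whole arrays such as RNA of other organs, and 200 genes were changed. Recovery in the real data may be lower, so comparisons without calls do not exclude 2-fold changes.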

Other observations

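The lists of small nucleolar RNA host genes and of cholesterol synthesis below were tests chosen only after the result was seen. In kidney at day 1, 6 of 9 small nucleolar RNA host genes rose (Gas5, Snhg12, Snhg4, Snhg6, Snhg8 and Zfas1; median 0.90); Snhg12 and Zfas1 prompted the list. The median was 0.22 at day 3 and 0.25 at day 7, and in heart at day 1 it was 0.25. Of 18 cholesterol synthesis genes, 2 fell in kidney at day 1 (Cyp51 and Idi1, which prompted the list; median -0.29), beside rises of Abca1 and Apoe, and 2 fell in heart at day 1 (Fdft1 and Nsdhl).

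Interferon response genes stood higher in replicate 1 of day 0 than in the other day 0 arrays of each tissue: by a median of 0.99 in heart (28 of 28 genes), 0.81 in kidney (25 of 28) and 0.38 in brain (22 of 27). Without it the list median went from -0.14 to 0.28 in heart at day 1, from -0.07 to 0.32 at day 7, from -0.41 to -0.12 in kidney at day 1 and from -0.23 to 0.12 at day 7. Brain day 0 replicate 1 also had Gh at 12.5, Prl at 10.4 and Alb at 10.7 on the log2 scale. Ano10 is measured by 1 probe set here.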
